A study of Mus musculus with 2 samples.

How the data were processed

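Gene expression was measured on 2 Agilent mouse two-colour arrays, each of which set RNA from autoreactive immature B cells (Cy5) directly against RNA from non-autoreactive ones (Cy3). Per the labels, the cells were pooled bone marrow cells sorted for B220 and against CD23, CD43 and IgD, 0.5 ug of total RNA per sample was amplified and labelled with Agilent's low-input linear kit, and the autoreactive cells carried the same dye on both arrays. The series design speaks of biological replicates, 2 in each group, while the sample labels number the autoreactive pools only and do not say which animals were pooled. The p-values therefore measure the spread between these 2 arrays, moderated by that of all probes tested. Strain, H-2 haplotype and dye followed the groups, and a Rag1 disruption is listed for the autoreactive cells alone, so none of these could be told apart from autoreactivity. Both arrays lay on 1 slide and shared a scan.

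The deposited scanner files hold mean spot intensity and median local background intensity per channel, extracted with Agilent Feature Extraction 9.5.1.1 per the file headers. The deposited log10 ratio of Cy5 over Cy3 was computed by that program from background-subtracted, dye-normalized intensity values, per the file headers. It also gives a p-value per spot from its error model, per the file headers, which was not used. The deposited table of the series holds the same log10 ratios, with a largest difference of 5e-10 from the scanner files, a median of 0 on each array, and an exact 0 at 29.3% of spots on array 1 and 30.4% on array 2. Its scale, centring and direction were therefore known from this match.

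Mean intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 (R 4.3.3, with data.table), with control spots and outlier spots given no weight. Outlier spots were then removed, spots of a probe were averaged, and a probe was tested when it was well above background in at least 1 channel on each array. This left 22613 of 41174 probes. Log2 ratios were tested against 0 with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. The fit had 1 residual degree of freedom per gene and a prior of 5.10 degrees of freedom. A gene was represented by its brightest probe, giving 15103 genes. Of 340 called genes with several tested probes, 311 had all probes on the same side.

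Probes were named through a RefSeq gene table of assembly GRCm38.p6, used for names alone. The main accession named 22944 probes, another RefSeq accession 121, a current symbol 6587 and a unique synonym 3077, and 8445 kept the name in the file. Probe positions are those of the scanner files, which name no genome build.

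A gene whose probe was not well above background in a channel on both arrays is given as a bound, the brighter channel's mean against the higher of the lowest signal well above background and the dim probe's own, per channel after loess and Aquantile scaling, a value open to dye bias. The 26 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are the 12 highest and 12 lowest called genes at least 2-fold changed on both arrays (clone and model names left out), up to 4 members with the largest absolute ratio in each list, and H2-Ea, Rag1, Rag2, Ptprc, Fcer2a, Spn, Ighd, Ighm and Igkc. Ighd and Igkc were not found under these names and were not analysed here, and 3 other named genes are not reported here. Lists were tested with camera (preset correlation 0.01), with an estimated correlation and with fry (directional, with its mixed test beside it), adjusted over the lists. Of 757 list members, 689 were detected. Regions were tested with Fisher's exact test, two-sided. Figures were drawn with matplotlib 3.10.9.

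The procedure was tested on 10 simulated data sets for the autoreactive against non-autoreactive comparison, each with 15103 genes, 200 of them changed, 50 at each fold size, besides a shifted list and a set of changed genes near H2-K1. Limma recovered 17.6% of genes changed 1.5-fold, 88.2% at 2-fold, 99.8% at 4-fold and 100% at 8-fold. Unchanged genes made up 11.0% of calls on average (4.52% to 17.3%), above the share aimed for, and the prior, simulated at 5.10 degrees of freedom, was estimated at 5.36 to 10.4. Camera called the shifted list in all 10 data sets and no other list. The simulated noise was independent between probes and every member of that list was shifted by 0.6. These runs therefore do not show how camera behaves on lists of co-varying genes or on smaller shifts.

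Alternatives were no background correction, the deposited ratios, normexp offset 16, median centring, other filters on dim probes, the mean over probes, a fit of the separate channels without pairing by array, a trended and robust variance, each array alone, 1.5-fold in place of 2-fold, and windows of 5 and 20 Mb. Slide or scan as a block could not be run, with 1 slide and a shared scan.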

Results

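Immature B cells of the 3-83Igi line carry a knocked-in antigen receptor that recognises class I molecules of the H-2b haplotype, so that cells maturing in BALB.B mice (H-2b) meet their antigen and those in BALB/c mice (H-2d) do not. The series asks how the autoreactive cells differ from the non-autoreactive ones. It holds 2 arrays, each with a pool of autoreactive cells (BALB.B, Rag1-/-) set directly against non-autoreactive cells (BALB/c), and 43379 gene spots per array. Between 54.1% and 57.4% of spots were well above background in a channel, and no spot was saturated. The number of arrays limits the precision. All log2 ratios are autoreactive over non-autoreactive, and errors are limma standard errors (SE, n = 2 arrays). With a prior of 5.10 against 1 residual degree of freedom, an SE rests mostly on the spread of all probes tested. Across genes, which are not independent replicates, the ratios of the 2 arrays correlated with r = 0.711 and rho = 0.611, and their SD was 0.36 on array 1 and 0.50 on array 2.

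The gene used to check the labels, H2-Ea, encodes a class II alpha chain whose promoter is deleted in the H-2b haplotype. Its log2 ratio was -5.22 on array 1 and -5.26 on array 2, which placed the H-2b cells in the Cy5 channel (limma adjusted p = 0.000187). Rag1, the recombinase gene disrupted in the autoreactive animals, was 17.6-fold higher in their channel, with log2 ratios of 4.25 and 4.02. Its 3 probes gave 1.04 to 4.14, and since the disrupted part of the gene is not stated, this ratio checks nothing about the genotype. Rag2, the partner of Rag1, was at least 2.14-fold higher, as it was not well above background in the non-autoreactive channel (limma adjusted p = 0.0115). This bound equals the measured ratio, so it depends on the normalization as that ratio does. The log2 ratio of Rag2 was 2.51 with the deposited ratios, and 0.65, below that bound, with median centring on detected probes, chosen after seeing the data. It was not called with separate channels (adjusted p = 0.0684).

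Of 15103 genes tested, 531 were higher and 396 lower in autoreactive cells by limma. Besides Rag1, the highest log2 ratios included those of Klra16 (3.98 ± 0.21), Klra4 (3.84 ± 0.27, 1.71 with normexp offset 16), Klra7 (3.39 ± 0.21) and Klra15 (2.74 ± 0.18), which encode Ly49 receptors of natural killer cells. Nyx, which encodes a retinal proteoglycan, stood at 3.69 ± 0.15. Its other probe, not well above background in non-autoreactive cells, was at least 1.52-fold higher, a bound equal to its measured ratio, and was not called. The other highest genes were the insulin receptor substrate gene Irs1 (2.81 ± 0.19, its other probe 0.92), the protamine gene Prm1 (2.80 ± 0.12) and the actin-bundling gene Pls1 (2.77 ± 0.13). Rasgef1a (2.77 ± 0.12), the orphan receptor gene Gpr176 (2.62 ± 0.16) and the dynein gene Dnah5 (2.52 ± 0.18) completed them. After H2-Ea, the lowest was Ppp1r14c, a phosphatase inhibitor gene at least 12.6-fold lower on a probe not well above background in autoreactive cells. Its other probe gave -0.051. Ms4a1, the gene of the B cell surface protein CD20, stood at -3.61 ± 0.20. Igh-VJ558 heavy chain variable sequences (-3.31 ± 0.12, with 3 of 5 probes called and the others close to 0), Rbm45 (-3.03 ± 0.12), and the lipid raft gene Rftn1 (-2.92 ± 0.12) were lower. So were Fgd2 (-2.75 ± 0.12), Plpp3 (-2.52 ± 0.15), Sord (-2.19 ± 0.21), the scavenger receptor gene Cd36 (-2.17 ± 0.14) and Pld4 (-2.10 ± 0.12). Limma adjusted p-values of these genes lay between 0.000187 and 0.00601.

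A change of at least 2-fold on both arrays was measured for 153 higher and 106 lower genes. Each array alone gave more, 212 higher and 142 lower on array 1 and 330 and 419 on array 2. The counts depended on the variance and scaling. A trended and robust variance called 354 higher and 11 lower genes. It ended 41 of 75 calls of named genes, among them Cd36, Sord, Pld4 and all lower ones given with an SE in the gene groups below. Separate channels gave 106 and 71 and ended 37 of the 75, Cd36 and Sord among them. Median centring gave 9922 and 377. The deposited ratios ended 21, those of Atp5a1, Atp5b, Atp5c1, B2m, Bcl2l1, Blnk, Ccl5, Ccng2, Cd8b1, Hemgn, Herpud1, Ighm, Irf4, Itgb7, Itpr1, Nek2, Pdia3, Slc4a1, Tap2, Traf1 and Xbp1. Another probe of the gene gave 1.60 for Klra4, 1.69 for Klra7, 1.67 for Rasgef1a, -0.60 for Ptprj, -0.93 for Cd86, -0.96 for Igll1 and -0.89 for Jchain. For Rftn1 it was not well above background in autoreactive cells and was at least 2.45-fold lower. It was not called, at 0.53 for Spred1, 0.48 for Pdk1, -0.75 for Ltf, -0.48 for Ptprc and -0.41 for Hemgn. Median centring put the median gene at 0.58 on each array and the medians of 17 lists on the other side of 0. Directions here are relative to the loess curve. In simulated data 11.0% of limma's calls were of unchanged genes.

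**Figure D1:**
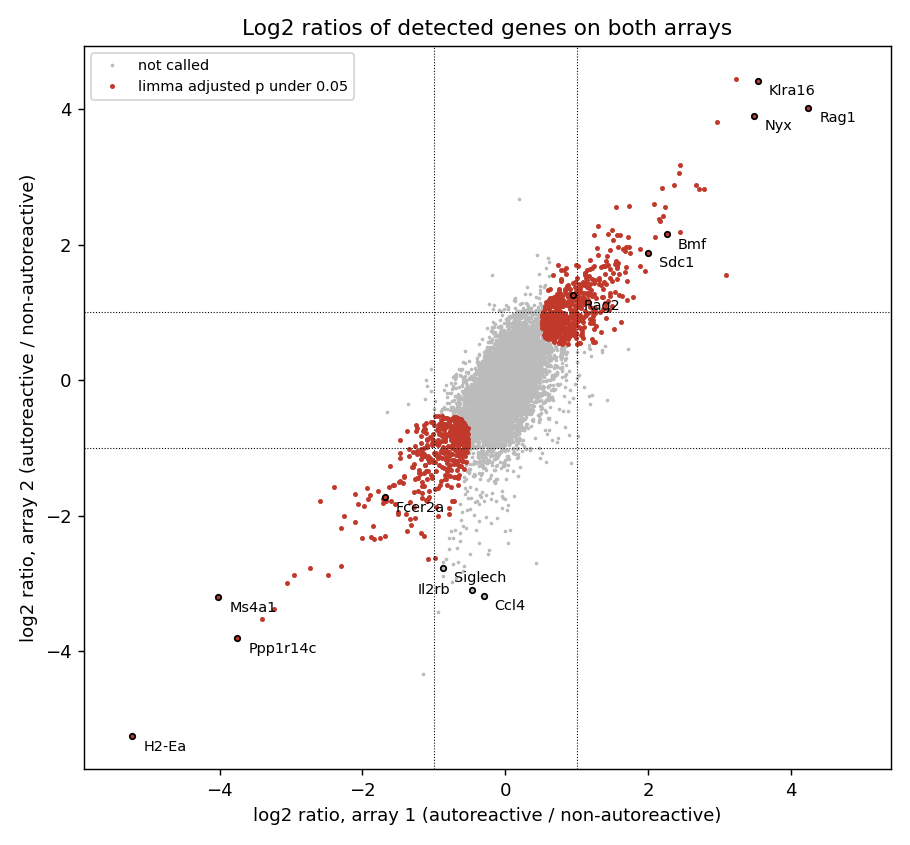
Log2 ratio (autoreactive over non-autoreactive) of each of 15103 detected genes on array 1 (x axis) against array 2 (y axis), with genes called by limma in red, others in grey, and dotted lines at 2-fold. H2-Ea (-5.22 and -5.26) and Rag1 (4.25 and 4.02) lie at the ends of the diagonal, while Il2rb (-0.47 and -3.10) and Ccl4 (-0.30 and -3.19) lie far below it.

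Genes of antigen presentation on class II molecules were lower in autoreactive cells. Of 17 detected members, 10 were lower and 1 higher by limma, with the same counts adjusted over the list alone. The 10 include H2-Ea, used to check the labels. Without it, an alternative chosen after seeing the data, 9 of 16 were lower and the median was -0.705 (camera adjusted p = 0.000513, adjusted p = 0.830 with an estimated correlation). Lower members included H2-Aa (-1.84 ± 0.13, its other probe -0.24), H2-Eb1 (-1.70 ± 0.13), the invariant chain gene Cd74 (-1.37 ± 0.13) and Ciita, the class II transactivator (-1.21), while H2-Ob was higher (1.34). The list's median log2 ratio was -0.77 on array 1 and -0.74 on array 2 (camera adjusted p = 4.08e-05, adjusted p = 0.830 with an estimated correlation). Of the members named here, H2-Eb1, H2-Ob and, by its other probe, H2-Aa lie within 1 Mb of H2-Ea, in the H-2 region that also differs between the strains. For these genes a difference of that region cannot be told apart from autoreactivity. The calls of H2-Aa, H2-Eb1 and Cd74 ended with a trended and robust variance, and Cd74 stood at -0.035 under median centring (adjusted p = 0.834). Class I genes went both ways, with 2 of 22 higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.356). Camera called this list as lower with the deposited ratios (adjusted p = 0.0185) and as higher under median centring (adjusted p = 0.0282). The transporter gene Tap2 (0.80 ± 0.13) and B2m (0.66 ± 0.12, 0.35 with the deposited ratios, though 1 of its probes gave -0.15) were higher, and the chaperone genes Pdia3 (-1.06 ± 0.19, -0.70 on array 1 and -1.43 on array 2) and Calr (-0.98 ± 0.14, above 0 under median centring) lower. Tap2 too lies within 1 Mb of H2-Ea, so a difference of that region cannot be told apart from autoreactivity for it either.

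Genes of transitional and mature B cells were lower as a group. By limma 8 of 28 detected members were lower and 2 higher (14 and 4 adjusted over the list alone), with a median of -0.28 (-0.28 on array 1 and -0.47 on array 2, camera adjusted p = 0.00224, adjusted p = 0.830 with an estimated correlation). On array 2 the markers of other cell types had a lower median too (-0.83, against -0.19 on array 1). The median of the mature B cell list was 0.053 with median centring on detected probes, chosen after seeing the data, which ended the call (camera adjusted p = 0.276). Besides Ms4a1, the chemokine receptor gene Ccr6 (-2.09 ± 0.16) and the BAFF receptor gene Tnfrsf13c (-1.94 ± 0.13) were lower. The integrin gene Itgb7 (-1.86 ± 0.34, -1.08 on array 1 and -2.63 on array 2, its call ended in 4 of 10 settings), the complement receptor gene Cr2 (-1.09) and Fcer2a, which encodes the CD23 excluded by the sort (-1.71 ± 0.12), were lower. Of the genes of other gate markers, Ptprc was lower (-0.85 ± 0.12) and Spn, which encodes CD43, stood at -0.030 ± 0.14 (limma adjusted p = 0.92). The heavy chain constant gene Ighm, whose product was not in the gate, was higher (1.00 ± 0.16, limma adjusted p = 0.023). With the deposited ratios Ighm stood at 0.41 (adjusted p = 0.264), and its call ended in 3 of 10 settings. Ptprc, which includes the B220 form, turned to 0.36 under median centring, as did Spn to 1.03.

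Early-stage genes went both ways. Of 26 detected pro-B and pre-B genes, 5 were higher and 4 lower (10 and 8 adjusted over the list alone, camera adjusted p = 0.870). The surrogate light chain genes Vpreb1 (-1.74 ± 0.15) and Igll1 (-1.45 ± 0.17) and the gene Arpp21 (-1.34 ± 0.14, -2.14 with the deposited ratios) were lower. Cplx2 (1.23) and Vpreb3 (0.85) were higher, and Tcf7 at -1.27 ± 0.30 did not pass. Recombination and editing genes included 4 higher and none lower of 25 (4 and 2 adjusted over the list alone, camera adjusted p = 0.269). These were Rag1, Rag2, the transcription factor gene Irf4 (0.89 ± 0.18, 1.23 on array 1 and 0.56 on array 2, its call ended in 6 of 10 settings) and the DNA end-binding gene Xrcc6 (0.73). Dntt at -0.98 ± 0.29 (-0.33 on array 1 and -1.64 on array 2) did not pass. Of 6 immunoglobulin and receptor chain genes, Ighm was higher and Jchain lower (-1.65 ± 0.20), 3 and 1 adjusted over the list alone (camera adjusted p = 0.361). The log2 level of Jchain in autoreactive cells (6.92) was close to the lowest signals well above background there (6.32 on array 1 and 6.79 on array 2). Plpp3 (7.22) and Ccr6 (7.46) were also near these signals, so the sizes of such ratios are uncertain. Cd79b (0.69 ± 0.15) and Iglv1 (0.96 ± 0.21) did not pass, and Iglv1 turned to -0.69 when its probes were averaged.

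Genes that antigen induces early included 8 higher and 1 lower of 41 detected (12 and 1 adjusted over the list alone). The phosphatase genes Dusp2 (1.41 ± 0.13) and Dusp6 (1.23), the Ras pathway inhibitor gene Spred1 (1.30 ± 0.13), and the transcription factor genes Egr2 (1.21), Egr3 (0.90) and Junb (1.11) were higher. The co-stimulatory gene Cd86 was lower (-1.48 ± 0.12), and the chemokine gene Ccl4 at -1.74 ± 0.60 did not pass. The list as a whole was not called, with medians of 0.35 on array 1 and -0.24 on array 2 (camera adjusted p = 0.187). It was called as higher with median centring on detected probes (median 0.33, camera adjusted p = 0.0343). PI3K and FoxO pathway genes were the list called as higher, with 7 of 32 members higher and none lower (8 and 2 adjusted over the list alone, median 0.08, camera adjusted p = 0.037, adjusted p = 0.830 with an estimated correlation). They included Rag1, Rag2, the cyclin gene Ccng2 (0.88 ± 0.13) and Il7r (0.68). Pdk1 (0.94 ± 0.12) was counted too, though this symbol is that of a pyruvate dehydrogenase kinase gene and not of the PI3K pathway kinase. The call ended with the deposited ratios (camera adjusted p = 0.0502), with probes well above background in both channels (camera adjusted p = 0.0901) and, chosen after seeing the data, without Rag1, Rag2 and Klra genes (camera adjusted p = 0.186).

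Inhibitory receptor and anergy genes were lower as a list, with 6 of 31 lower and 1 higher (19 and 2 adjusted over the list alone, median -0.43, camera adjusted p = 1.04e-05, adjusted p = 0.830 with an estimated correlation). Lower were the phosphatase gene Ptprj (-1.73 ± 0.12), Cd5 (-1.49 ± 0.12), a marker of chronic receptor signalling in other settings, Pirb (-1.42 ± 0.18) and Pdcd1 (-1.34 ± 0.13, -2.51 with the deposited ratios). Lax1 was higher (1.07). B cell receptor signalling components had 5 lower and 2 higher of 42 (13 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.0185, adjusted p = 0.830 with an estimated correlation). The scaffold gene Bank1 (-1.29 ± 0.12) and the calcium channel gene Itpr1 (-0.76 ± 0.13, above 0 under median centring) were lower. The adaptor gene Blnk was higher (1.08 ± 0.12), though not called with the deposited ratios (0.76, adjusted p = 0.0577). Trafficking genes had 5 lower and 1 higher of 26 (10 and 3 adjusted over the list alone, medians -0.094 on array 1 and -0.40 on array 2, camera adjusted p = 0.0289, adjusted p = 0.830 with an estimated correlation). The higher one was Rgs2 (1.79 ± 0.13, its other probe 0.52 and not called). Markers of other cell types also had lower medians on array 2 (-0.83, against -0.19 on array 1), and Ccr9, a trafficking gene, is a plasmacytoid dendritic cell marker too. Median centring ended the call of the B cell receptor signalling list (median 0.61, camera adjusted p = 0.237, with the median gene at 0.58). On detected probes it also ended the trafficking call (camera adjusted p = 0.423).

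Among apoptosis and survival genes, the pro-apoptotic gene Bmf was higher (2.21 ± 0.12, its other probes down to 0.66), as was the survival gene Bcl2l1 (0.63 ± 0.12, its other probes 0.39 and 0.27), and Traf1 was lower (-0.89 ± 0.16). This gave 2 higher and 1 lower of 33 (3 and 1 adjusted over the list alone, camera adjusted p = 0.684). The call of Bcl2l1 ended in 6 of 10 settings, and Pim2 at 0.61 ± 0.13 did not pass. Cytokine receptor and BAFF family genes had 5 higher and 4 lower of 32 (7 and 12 adjusted over the list alone, camera adjusted p = 0.187). The signalling inhibitor gene Socs1 (1.28 ± 0.14) and Il2ra (1.14) were higher, and Cd180 was lower (-1.42 ± 0.22, its other probe -0.055). Tlr7 at -1.24 ± 0.27 did not pass. In the plasma cell list 4 of 16 genes were higher and 3 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.870). Sdc1 (1.94 ± 0.12) and the stress response gene Herpud1 (1.24 ± 0.20) were higher. Unfolded protein and heat shock genes had 1 higher and 1 lower of 23 (4 and 3 adjusted over the list alone, camera adjusted p = 0.730), Herpud1 and Xbp1 (-0.80 ± 0.13). Median centring on detected probes made this list higher (camera adjusted p = 0.00964). Hspa1a (1.02 ± 0.25) and Hspb1 (0.63 ± 0.17) did not pass.

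Genes of the G2 and M phases had a median of -0.32 (-0.15 on array 1 and -0.53 on array 2, camera adjusted p = 1.04e-05, adjusted p = 0.830 with an estimated correlation). Markers of other cell types also had lower medians on array 2 (-0.83, against -0.19 on array 1). By limma only Nek2 (-0.77 ± 0.14, above 0 under median centring, its call ended in 6 of 10 settings) of 39 was lower, and none was called adjusted over the list alone. Top2a (-0.69 ± 0.19), Plk1 (-0.61 ± 0.13) and Ube2c (-0.58 ± 0.17) did not pass and were above 0 under median centring. None of 38 S phase genes was called, over all genes or adjusted over the list alone (medians -0.063 on array 1 and -0.23 on array 2, camera adjusted p = 0.0711). Pcna stood at 0.59 ± 0.13, Ccne2 at 0.48 ± 0.28 and Uhrf1 at -0.40 ± 0.15 (above 0 under both centrings). Median centring ended the G2 and M call (median 0.62, camera adjusted p = 0.0843, with the median gene at 0.58). Camera called the S phase list as higher under median centring (median 0.86, adjusted p = 0.000658). It called this list as lower with the deposited ratios (adjusted p = 0.00517), with probes of any brightness (adjusted p = 0.01021) and with the mean over probes (adjusted p = 0.03035). Glycolysis and oxidative phosphorylation genes had 3 higher of 38 and none lower, also adjusted over the list alone (camera adjusted p = 0.249). They were the ATP synthase genes Atp5b (0.90 ± 0.13), Atp5a1 (0.74 ± 0.12) and Atp5c1 (0.65 ± 0.12). With the deposited ratios they stood at 0.54, 0.33 and 0.23 and none was called, and their calls ended in 3, 4 and 4 of 10 settings. Other probes of Atp5b and Atp5a1 gave as little as 0.096 and 0.020, and Cox6c at 0.56 ± 0.16 did not pass. Interferon-stimulated genes had 2 higher and 2 lower of 36 (2 and 7 adjusted over the list alone, median -0.21, camera adjusted p = 0.00542, adjusted p = 0.830 with an estimated correlation). Ifi27 was higher (1.16 ± 0.13, its other probe 0.31 and not called), Oas2 was lower (-1.29 ± 0.13) and Bst2 at -1.53 ± 0.35 did not pass. Centring on detected probes ended the call (camera adjusted p = 0.0542).

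Markers of plasmacytoid dendritic, T, myeloid and erythroid cells were lower as lists, with lower medians on array 2. Plasmacytoid dendritic cell markers had medians of -0.70 on array 1 and -1.83 on array 2. Of 19 members, 5 were lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 4.24e-07, adjusted p = 0.830 with an estimated correlation). Atp1b1 was higher (1.91 ± 0.12). Siglech (-0.87 and -2.77 on the 2 arrays), Ccr9 (-0.87 and -2.69) and Klk1 (-0.82 and -2.64, its other probe averaging -0.30) did not pass. Markers of T cells had medians of -0.28 and -0.81, with 3 of 18 lower (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00028, adjusted p = 0.830 with an estimated correlation). Among them was Cd8b1 (-0.93 ± 0.16, its call ended in 5 of 10 settings), on a probe placed on chromosome 5 in the scanner files. Its other probe, on chromosome 6 where the gene lies, gave -2.26. Thy1 at -1.08 ± 0.41 (-0.12 on array 1 and -2.03 on array 2) did not pass. In the myeloid and granulocyte list the medians were 0.035 and -0.81, with 3 of 30 lower (4 adjusted over the list alone, camera adjusted p = 2.50e-05, adjusted p = 0.830 with an estimated correlation). Wfdc21 (-1.18 ± 0.19) and Ltf (-0.84 ± 0.17, -0.56 on array 1 and -1.13 on array 2) were lower, and Cybb (-0.79 ± 0.23) and Camp (-0.69 ± 0.19) did not pass. Ltf and Camp were above 0 under median centring, which ended the call of the list (camera adjusted p = 0.079). Erythroid markers had medians of -0.29 and -0.43, with 2 of 24 lower (13 adjusted over the list alone, camera adjusted p = 6.80e-06, adjusted p = 0.830 with an estimated correlation). These were Slc4a1 (-0.75 ± 0.15) and Hemgn (-0.69 ± 0.14), whose calls ended in 6 and 7 of 10 settings. Trim10 (-0.64 ± 0.15) and Car1 (-0.58 ± 0.12) did not pass.

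Natural killer cell markers split, with 4 Klra genes higher and Ccl5 lower (-1.81 ± 0.35) of 21, 4 and 2 adjusted over the list alone (medians -0.0072 and -1.22, camera adjusted p = 0.151). Ccl5 stood at -0.99 on array 1 and -2.63 on array 2 and its call ended in 5 of 10 settings, and Il2rb at -1.79 ± 0.55 did not pass. None of 11 stroma and endothelium markers was called (4 lower adjusted over the list alone, camera adjusted p = 0.187). Col1a1 stood at -1.11 ± 0.30, Col1a2 at -0.81 ± 0.20, Bglap at -0.63 ± 0.14 and Cdh5 at -0.61 ± 0.13. None of 15 megakaryocyte, basophil and mast cell markers was called either, also adjusted over the list alone (camera adjusted p = 0.684). Hdc stood at -0.50 ± 0.19 (above 0 under median centring), Fcer1a at 0.36 ± 0.13, Ppbp at 0.36 ± 0.13 and Gata2 at -0.29 ± 0.20. Median and mean differed in sign for the early-stage list (0.11 and -0.094), the antigen-induced list (-0.053 and 0.072), apoptosis and survival (-0.018 and 0.014), plasma cell genes (-0.11 and 0.036) and megakaryocyte, basophil and mast cell markers (-0.011 and 0.015). Of all 26 lists, camera called 11 as lower and 1 as higher. None was called with an estimated correlation or with the directional test of fry, whose lowest adjusted p was 0.182. With 1 residual degree of freedom both tests had little power, so this lack of calls decides little. The estimated correlation was 0.74 for the myeloid, 0.71 for the G2 and M, 0.58 for the T cell and 0.44 for the plasmacytoid dendritic cell list. For the other lists called by camera it lay between -0.037 and 0.18. These estimates are themselves imprecise. Where genes co-vary so far above the preset 0.01, camera's p-values at that preset are too low. Fry's mixed test, which asks for changes in either direction, passed for PI3K and FoxO genes (adjusted p = 0.0121), class II genes (adjusted p = 0.0431) and recombination and editing genes (adjusted p = 0.0431). The first and last of these lists hold Rag1 and Rag2, and without H2-Ea the class II list did not pass (adjusted p = 0.0653). Median centring added camera calls of glycolysis and oxidative phosphorylation (adjusted p = 3.74e-05) and recombination and editing (adjusted p = 0.0107) as higher, and of natural killer cell (adjusted p = 4.77e-07) and stroma markers (adjusted p = 0.00471) as lower. Without the markers of other cell types, an alternative chosen after seeing the data, 526 genes were higher and 382 lower. These counts only drop the listed markers from the calls, with no new fit. They do not show whether the remaining calls depend on other cell types.

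**Figure D2:**
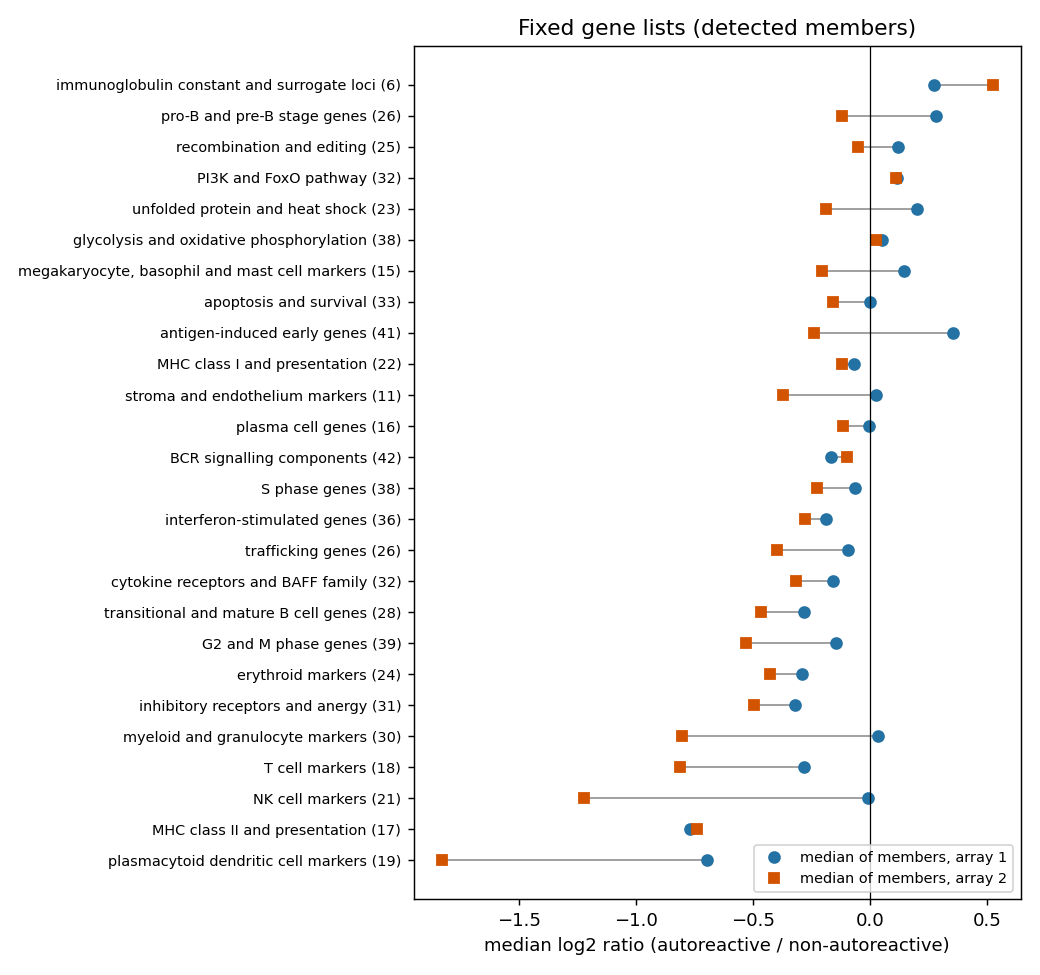
Median log2 ratio (autoreactive over non-autoreactive, x axis) of the detected members of each of 26 gene lists, with their number in brackets, on array 1 (circles) and array 2 (squares), joined by a line. Class II genes had similar medians on the arrays (-0.77 and -0.74), while plasmacytoid dendritic cell markers had -0.70 and -1.83.

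Called genes were more frequent near H2-K1, in the region that differs between the strains. Near Rag1, whose disruption is listed for the autoreactive cells alone, the excess rested in part on Rag1 and Rag2 themselves. Within 10 Mb of H2-K1 on chromosome 17, 37 of 372 genes were called (9.95%), against 6.06% elsewhere (odds ratio 1.71, 95% interval 1.18 to 2.43, Fisher's exact p = 0.0042, two-sided). Within 10 Mb of Rag1 on chromosome 2, 10 of 79 genes were called (12.7%), against 6.13% elsewhere (odds ratio 2.22, 95% interval 1.02 to 4.35, Fisher's exact p = 0.0293). Without Rag1, Rag2 and H2-Ea, an alternative chosen after seeing the data, it was 8 of 77 genes near Rag1, which did not pass (odds ratio 1.78, 95% interval 0.736 to 3.72, Fisher's exact p = 0.145), and 36 of 371 near H2-K1 (odds ratio 1.67, Fisher's exact p = 0.006). By the positions in the scanner files, whose build is not named, the Rag1 probe spans 101489372 to 101489431 on chromosome 2 and the H2-Ea probe 32421735 to 32421794 on chromosome 17. On chromosome 17 the probe of Fgd2 starts at 27571245, within 5 Mb of H2-Ea, and that of Rftn1 at 48142075, within 20 Mb. Bmf, Spred1, Gpr176, Ptprj and Pdia3 are also on chromosome 2, outside the window of 10 Mb and inside that of 20 Mb, and Dusp2 and Sord lie outside both. With windows of 5 and 20 Mb the odds ratios were 3.72 (Fisher's exact p = 0.00312) and 2.14 (p = 0.000315) near Rag1, and 2.52 (p = 2.66e-05) and 1.39 (p = 0.0432) near H2-K1. Without the 3 genes they were 2.79 (Fisher's exact p = 0.0303) and 2.00 (p = 0.00132) near Rag1, and 2.45 (p = 4.74e-05) and 1.36 (p = 0.0649) near H2-K1. With the deposited ratios the one near Rag1 was 3.49, and with probes of any brightness the one near H2-K1 was 2.81 and that near Rag1 did not pass (2.04). With a trended and robust variance neither odds ratio passed the test (1.23 and 1.58), and the one near Rag1 was 0.944 under median centring.

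**Figure D3:**
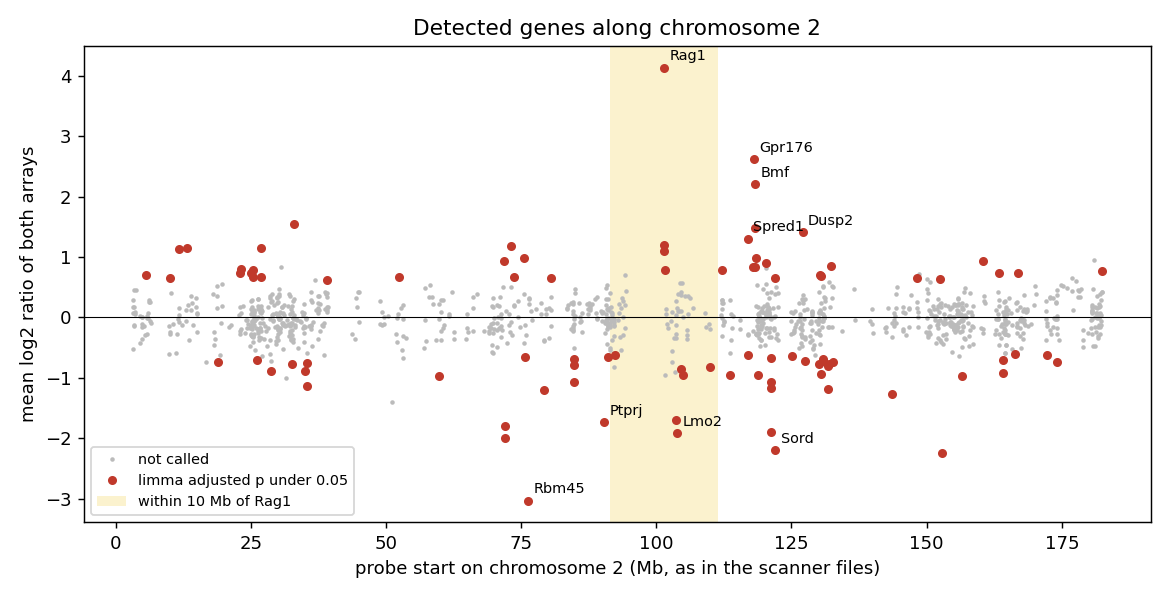
Mean log2 ratio of both arrays (y axis) of detected genes by probe start on chromosome 2 in Mb (x axis), as in the scanner files, with genes called by limma in red and the window of 10 Mb around Rag1 shaded. Rag1 stands at 4.14, and Gpr176 (2.62) and Bmf (2.21) lie to its right, outside the window.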

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

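Alternatives chosen after seeing the data were median centring on detected probes, the bins without clone and model names, the counts without some genes, the lists without Rag1, Rag2 and Klra genes, the regions and the class II list without Rag1, Rag2 and H2-Ea, and all alternatives for the correlation of the arrays. Of 75 named genes called by limma, 24 kept their call under all 10 distinct settings with a test, among them Ms4a1, Klra16, Dusp2, Spred1 and Sdc1. The trended and robust variance ended 41 of these calls and the fit of separate channels 37. With 2 arrays, each array alone lies within the SD of their mean by construction, so leaving out an array says nothing about named genes. With probes of any brightness kept, 27587 genes were tested and 244 were lower. Whether the limited signal of dim genes or the larger number of tests changed this count was not tested. Slide or scan as a block was not run, with 1 slide and a shared scan.

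The deposited ratios, in the scanner files and in the series table alike, gave 300 higher genes, and 197 lower at 2-fold on both arrays. Without the replicate block, which is the pairing of channels by array, 106 genes were higher and 71 lower, and Rag2, at 1.099, was no longer called. With trended and robust variance 11 were lower. A rule of 1.5-fold gave 473 higher and 367 lower genes. Each array alone gave 212 to 330 genes at 2-fold higher and 142 to 419 lower, and a myeloid median of -0.81 to 0.035. With an estimated correlation 0 lists were called, and with directional fry 0, tests that could hardly call any with 1 residual degree of freedom. Apart from this and the lower bar of the 1.5-fold rule, the cause of these changes was not tested.

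The odds ratio near Rag1 did not pass the test without Rag1, Rag2 and H2-Ea (1.778), with probes of any brightness (2.04), with both channels above background (1.77), without the replicate block (2.23), with trended and robust variance (1.58) or with median centring on detected probes (1.27), and was 0.944 under median centring. Near H2-K1 it did not pass with trended and robust variance (1.23), median centring (1.14) or median centring on detected probes (1.11). The cause was not tested.

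Median centring over all spots left ratios that depended on brightness, with medians from 0.057 in the dimmest to 0.96 in the brightest of 5 classes on array 1, so that 9922 genes were called higher, and 1648 were past 2-fold higher and 38 lower. On detected probes it gave 2790 higher, 2504 lower and 426 past 2-fold higher. The correlation of the arrays was 0.827 under both. Over all spots and on detected probes it ended the calls of G2 and M phase genes (medians 0.62 and 0.080, camera adjusted p = 0.0843 and 0.21) and B cell receptor signalling (0.61 and 0.076, camera adjusted p = 0.237 and 0.23). Tests passed as higher for S phase genes (0.86 and 0.33) and class I genes (0.99 and 0.45). On detected probes they also passed as higher for antigen-induced early genes (0.33) and unfolded protein and heat shock genes (0.44), and as lower for megakaryocyte, basophil and mast cell markers (-0.30). Over all spots Itpr1 turned to 0.020, Ltf to 0.40, Camp to 0.53, Calr to 0.076, Nek2 to 0.14, Plk1 to 0.53, Ube2c to 0.53, Uhrf1 to 0.84, Ptprc to 0.36 and Spn to 1.03 (0.50 on detected probes). Averaging the probes of a gene turned Iglv1 to -0.69, whose probes lie on both sides of 0.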

Other observations

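Apart from that of all genes in chromosome bins, the tests here were chosen after the results they bear on had been seen. Probes for immunoglobulin variable regions, taken by their descriptions, differed by locus. Of 20 tested, 2 were higher and 9 lower in autoreactive cells by limma. All 6 lower lambda probes were Iglv1 probes, from -1.31 to -1.08, while the 2 other Iglv1 probes stood at 0.77 and 0.96 and did not pass. The 3 lower heavy chain probes were Igh-VJ558 probes (-3.31, -2.92 and -2.33), and the 2 higher probes were kappa probes (0.83 and 1.35).

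A hypothesis of chromosome segments inherited from different strains was tested by counting 2-fold genes in bins of 10 Mb outside the H-2 and Rag1 windows, and in 2 of 270 bins the excess over the genome share (219 of 13256 genes) passed the adjusted test. On chromosome 16, from 10 to 20 Mb, it was 10 of 110 genes (one-sided Fisher's exact adjusted p = 0.0037), among them Prm1, Socs1, Ciita, Igll1 and Vpreb1, and on chromosome 1, from 80 to 90 Mb, 6 of 57 (one-sided Fisher's exact adjusted p = 0.0461), which were Irs1 and Dgkd, both higher, and the clone and model names A530032D15Rik, A530040E14Rik, C130026I21Rik and LOC545342, all lower (-3.47 to -1.27) and within 1 Mb. Whether these 4 are related copies was not tested. Without clone and model names, an alternative chosen after seeing the data, 0 of 269 bins passed, with 8 of 87 genes in the bin on chromosome 16 (one-sided Fisher's exact adjusted p = 0.0654) and 2 of 37 in that on chromosome 1. Neighbouring genes that are regulated together would give such bins too, and the strains' sequences were not analysed here.

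Of 13 Klra genes tested, 6 were higher and 1, Klra20, was lower (-0.94). More natural killer cells in the autoreactive sorts were argued against by the other 17 markers of that type, of which 0 lay above 0 and whose median was -0.74 (bootstrap 95% interval -1.12 to -0.47, medians of -0.044 and -1.33 on the 2 arrays). Differences between the strains in the Klra genes or under their probes, and regulation in autoreactive cells, may each remain and were not tested.

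By limma 5 of 19 plasmacytoid dendritic cell markers, 3 of 18 T cell, 3 of 30 myeloid and 2 of 24 erythroid markers were lower, and these lists were called by camera but not with an estimated correlation (adjusted p = 0.830). A dye bias equal on both arrays was argued against, as the source of the whole pattern, by the medians of 107 markers, -0.19 on array 1 and -0.83 on array 2, whose difference of -0.64 lay outside the central 95% of 10000 random lists matched on brightness (-0.11 to 0.053). A purer autoreactive sort that lowers every type alike was tested with the median of plasmacytoid dendritic cell markers, which lay at -0.92 from that of erythroid markers (bootstrap 95% interval -1.27 to -0.40). Among plasmacytoid dendritic, T, natural killer (without Klra genes), myeloid and erythroid markers, these were the lowest and highest medians. The interval takes no account of that choice, so it argues only weakly against an equal lowering. The bootstrap treats the genes of a list as independent. A purer sort need not lower all types alike, so this does not decide about purity in general. Part of the first list, such as Spib, Irf8, Tcf4 and Ly6d, is also expressed by B cells. A loss of single cell types from the autoreactive sort, more so on array 2, may remain and was not tested, though the gate for B220 would remove T, myeloid and erythroid cells that lack it.

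By limma 8 of 28 mature B cell genes and 10 of 17 class II genes were lower and Rag1 and Rag2 higher, while neither list was called with an estimated correlation (adjusted p = 0.830) and the median of the first was 0.053 with median centring on detected probes. Hybridisation differences of single probes cannot be told apart from a difference in expression: of the 5 called genes with several probes 100% had them on one side, but so did 311 of all 340 such genes, and every probe was called in only 3 of the 5, H2-DMb2, Ms4a1 and Rag1, and not in H2-Aa (other probe -0.24) or H2-Ab1. Leftover mature B cells in the non-autoreactive sorts, which the gate against CD23 would remove, were tested with Fcer2a, whose ratio lay 1.91 above that of Ms4a1 (2.335 on array 1 and 1.477 on array 2). Its level in autoreactive cells was only 1.07 on the log2 scale above the lowest signal well above background, so this explanation cannot be told apart from a difference within immature cells. Autoreactivity, strain, H-2 haplotype, dye and the Rag1 disruption may each contribute and are confounded by the design.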
